A study of Homo sapiens with 6 samples.

How the data were processed

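The samples were 6 libraries of LX2 cells, an established human hepatic stellate cell line, grown in medium with 2% serum and collected 36 h after transfection. A control siRNA (siNC) was used for 3 libraries and an siRNA against SHMT2 (siSHMT2) for the other 3. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Untransfected cells were not analysed here, and neither siRNA sequence is given in the sources used here.

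The authors deposited 1 table of FPKM values (fragments scaled to gene length and library total) for 60623 genes, with gene coordinates, lengths and biotypes. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the hg18 build were used; per the labels, libraries were made from total RNA with a SMARTer mRNA kit. The coordinates in the table did not bear out hg18: of 58457 gene identifiers shared with GENCODE release 29 (GRCh38), 99.9% lay on the same chromosome and overlapped, and 79.6% had identical start and end. Coordinates are therefore given as in the table, which match GRCh38. Strand use in counting is not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical copies, cannot be told apart.

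In every library FPKM times gene length was a whole multiple of 1 step (100% of values above 0, within 0.02 of a whole number), which gave back whole reads and the total used for scaling. Recovered reads summed to between 14722344 and 15669139 per library. The totals behind the FPKM were 0.957 to 1.13 times these sums, from 14487813 to 17495471, so the authors' totals were rescaled by a method not given in the sources used here. The deposited unit is FPKM, so no count model was used for the main results.

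Genes with a mean FPKM of at least 1 over the 6 libraries were tested (10865 genes, 9489 of them protein-coding). The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with variances moderated along an intensity trend, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. All fold changes are differences on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists with at least 5 tested members were tested with limma camera at a preset correlation between genes of 0.01. They were tested again with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries instead of the number of genes. Far larger differences are then needed for a call, whatever the correlation. SHMT2 alone was also compared by an exact permutation test, two-sided.

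The tests, alternatives, 45 gene lists and naming rule were fixed before the data were examined. The rule named SHMT2, the 10 largest rises and the 10 largest falls among called protein-coding genes whose groups did not overlap, and up to 4 tested members with the smallest adjusted p of each list described. ACTA2, COL1A1, COL1A2, COL3A1, TIMP1, TGFB1, MTHFD2, SHMT1, PHGDH, ATF4, MKI67 and CDKN1A were always named where tested. ACTA2 and SHMT1 lay below the filter and are given as values only. Some genes that the rule names are not reported here.

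Alternatives covered the pseudocount, the filter, scaling, gene biotype, moderation, library weights, a replicate block, the correlation used by camera, and leaving out each library. Further alternatives were chosen after seeing the data: limma voom on recovered reads, with and without quality weights, FPKM recomputed from the read sums, removal of each library's trend on transcript GC content (loess, span 0.5), and a fit to genes whose 3′ UTR held neither of 2 leading words. The last kept SHMT2 and only protein-coding genes whose 3′ UTR was searched for words. Noncoding and unsearched genes were thus left out as well. Words of 7 bases were taken from the longest annotated 3′ UTR of each gene in GENCODE release 29, which was at least 50 bases long for 9385 tested protein-coding genes besides SHMT2 (98.9%). The log2 fold change was regressed on the presence of each possible word, with log2 3′ UTR length and 3′ UTR GC content in the model, in Python with numpy and scipy.

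The fits were tested on simulated data. Reads were drawn for the 10865 tested genes of the siSHMT2 and siNC comparison with 200 changed genes in each of 5 draws. Genes changed 1.5-fold were called in 27.5% of cases, those changed 2-fold in 79.7% and those changed 4-fold in 99.4%, with 0 wrong directions, and 0.0958% of unchanged genes were called. A list shifted by a known amount was called in 5 of 5 draws, and 0 unshifted lists were called. Genes were drawn independently, with the same spread in both groups. These draws therefore do not test camera on lists whose members vary together. For the word test on 9385 genes, 0 words were called with no effect planted, and a word planted at -0.1 on the log2 scale ranked 1 of all words. Fold changes were shuffled between genes there, which removes any link with 3′ UTR length or base content. Word calls that arise from such a link were therefore not tested.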

Results

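RNA was measured in LX2 cells, a human hepatic stellate cell line used as a model of the collagen-producing cells of liver fibrosis, 36 h after transfection with a control siRNA (siNC, 3 libraries) or an siRNA against SHMT2 (siSHMT2, 3 libraries). SHMT2 encodes the mitochondrial serine hydroxymethyltransferase, which turns serine into glycine and charges folate with a carbon unit. The deposited FPKM values corresponded to 14722344 to 15669139 recovered reads per library. The first principal component held 53.2% of the variance and separated the groups. The siNC libraries were further apart (median SD 0.191 on the log2 scale) than the siSHMT2 libraries (0.105).

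SHMT2 (chromosome 12, 57229573 to 57234935 in the table, matching GRCh38) was depleted in every siSHMT2 library. Its FPKM was 40.8, 56.3 and 45.1 in the siNC libraries, from 3277, 3747 and 3258 reads, and 2.26, 2.10 and 2.42 in the siSHMT2 libraries, from 166, 160 and 176 reads. The siSHMT2 mean was 4.77% of the siNC mean. On the log2 scale SHMT2 fell by 3.88 (SE 0.132, limma adjusted p = 2.08e-05). The exact permutation test of 3 against 3 libraries gave p = 0.1, the smallest it allows.

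Cells given siSHMT2 had lower transcripts of inflammatory cytokines, interferon-response genes, YAP targets, matrix proteases and mitotic genes by camera at the preset correlation. These 5 list calls were lost with an estimated correlation (adjusted p = 0.0775, 0.174, 0.248, 0.174 and 0.231, in that order), and splits of the libraries that mixed the groups called up to 12 lists. Each mixed split keeps part of the siRNA difference, so those calls do not show how many lists would be called without one. The estimated correlations of the 5 lists were -0.0219, 0.0912, 0.263, -0.0524 and 0.107, in the same order. For cytokines and proteases they lay below the preset value, so a higher correlation between members does not account for those losses. That test also has far fewer degrees of freedom, so a loss in it does not show that members vary together. Of the genes tested, 659 were higher and 1070 lower in siSHMT2 by limma, and 57 were higher and 210 lower by at least 2-fold. After SHMT2, the largest falls were in IL1B, a proinflammatory cytokine (170.5 ± 21.4 to 17.8 ± 1.36 FPKM, SD, n = 3), and PTX3, a secreted pattern-recognition protein (161 ± 9.10 to 22.4 ± 2.17). CLDN11, a tight-junction protein, CSF2, a colony-stimulating factor, and CXCL8, a neutrophil chemokine, fell by 2.73, 2.73 and 2.71 on the log2 scale. NAA50, an N-terminal acetyltransferase, FSTL1, HSD17B11 and the cochaperone BAG3 fell by 2.55, 2.36, 2.15 and 2.15.

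Among called protein-coding genes, the largest rise on the log2(FPKM + 1) scale was in TPM4, a tropomyosin of the actin cytoskeleton. Its mean went from 22.3 ± 1.68 to 86.2 ± 2.75 FPKM (SD, n = 3), a log2 fold change of 1.91 (SE 0.106, limma adjusted p = 0.000118). MED11, a Mediator subunit, CHST14, a dermatan sulfotransferase, GANAB, the catalytic subunit of glucosidase II, and TOMM22, an import receptor of the outer mitochondrial membrane, rose by 1.88, 1.77, 1.72 and 1.65. TUFT1, GOLGA2, OGFR, HABP4 and ZNF629 rose by 1.45, 1.44, 1.43, 1.40 and 1.40.

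**Figure D1:**
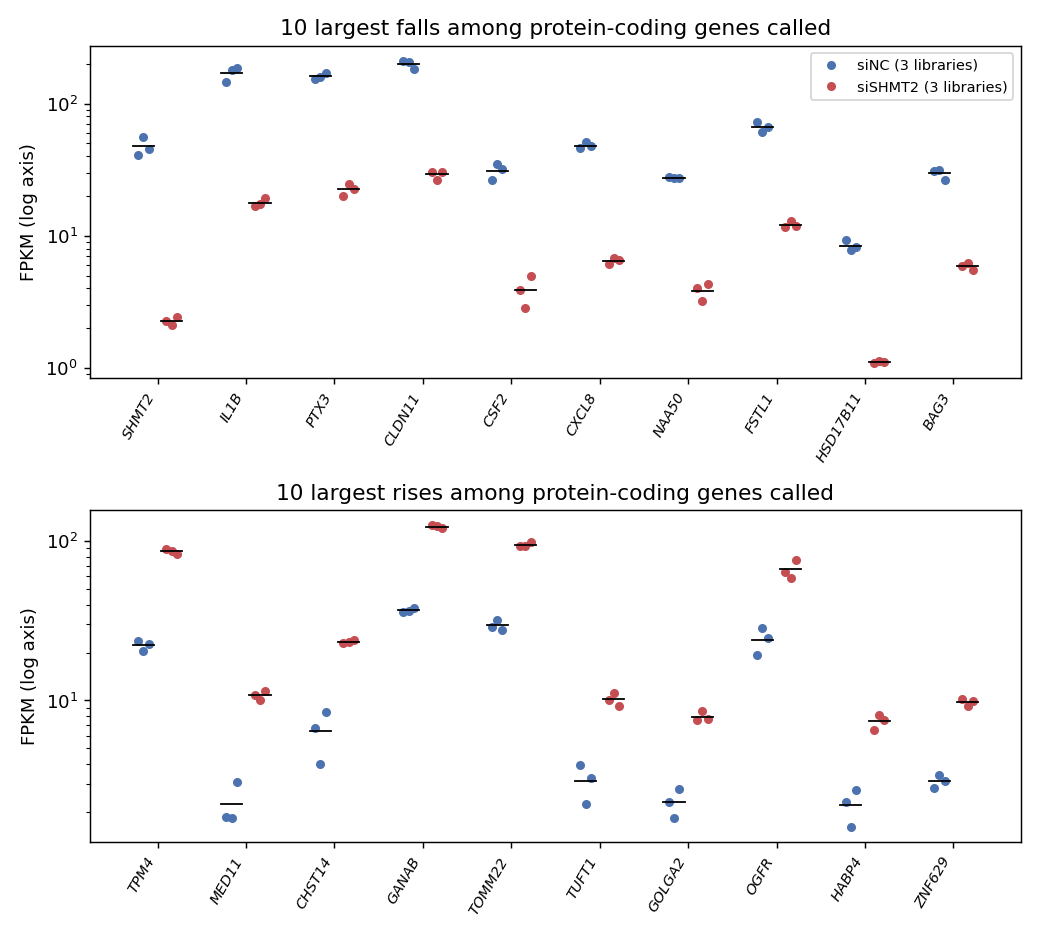
FPKM per library (log axis) of the 10 largest falls and 10 largest rises among called protein-coding genes, with siNC in blue, siSHMT2 in red and group means as black bars. The 3 values of each group lie apart for every gene shown; IL1B went from a mean of 170.5 to 17.8 and TPM4 from 22.3 to 86.2.

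The groups did not overlap for 3958 tested genes (36.4%, against 10% by chance). The counts depended on the libraries: without siSHMT2 replicate 1, 2 or 3 in turn, 229, 282 or 246 genes were higher and 498, 592 or 547 lower. They also depended on the processing: array weights gave 1827 higher and 1976 lower and the replicate block 374 and 696, while a pseudocount of 0.1 gave 99 higher and 402 lower by at least 2-fold and voom on recovered reads 115 and 418. The share of lower genes among calls was 61.9%, but 47.5% after rescaling to TPM (686 higher, 620 lower), which moved the median of all genes to 0.109, and 49.1% with FPKM from plain read sums (796 higher, 767 lower).

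Genes lower in siSHMT2 often held the word GACTTTA or ACTTTAA in the 3′ UTR. Of all words tested, these 2 went most strongly with lower fold change. They were picked on these same fold changes, so the shares and counts below describe that choice and do not test it. Either word was present in 553 of 961 searched genes called lower (57.5%), in 62 of 590 called higher (10.5%) and in 1694 of 7834 not called (21.6%). These shares are not adjusted for 3′ UTR length or base content: the median 3′ UTR had 1952 bases and 38.0% GC in genes called lower, 1493 bases and 48.2% in genes called higher and 1244 bases and 43.7% in genes not called. Among genes called at least 2-fold lower, 120 of 179 (67.0%) held one, with a median of 1742 bases and 36.8% GC. Of the 9 largest falls besides SHMT2, 7 held one (PTX3, CLDN11, CXCL8, NAA50, FSTL1, HSD17B11 and BAG3), as did 1 of the 10 largest rises, CHST14. Among the 7076 genes with neither word the median log2 fold change was 0.06, with 408 called lower and 528 higher. GACTTTA also occurs in the coding sequence of SHMT2.

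**Figure D2:**
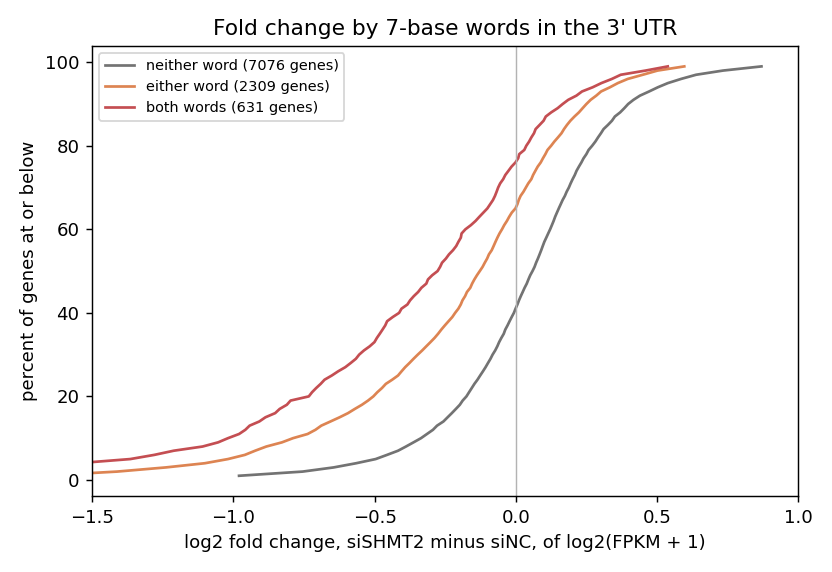
Cumulative percent of searched protein-coding genes at or below each log2 fold change (siSHMT2 minus siNC), for genes with neither word (7076), either word (2309) and both words (631) in the 3′ UTR. The medians lie at 0.06, -0.13 and -0.28. The words were picked on these same fold changes.

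Cytokines and other NF-kB targets fell as a group, with 15 of 22 tested members lower and 0 higher (17 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.18e-09, and adjusted p = 0.0775 with an estimated correlation). CXCL8, IL1B and CSF2 led them, with SOD2, the mitochondrial superoxide dismutase (fell by 1.35). Of the 15, 3 held either word, CXCL8 and SOD2 among them, and the 18 members without one had a median of -0.54. A list of senescence-associated secretion, which shares CXCL8 and IL6 with the cytokines, held secreted factors and other genes such as the cell cycle inhibitor CDKN1A. It had 6 of 17 members lower (7 adjusted over the list alone; camera adjusted p = 0.00711, and adjusted p = 0.231 with an estimated correlation). Each of the 6 also stands in another list. The cytokine IL6 fell by 1.57. That list was not called among genes without the words (adjusted p = 0.0613), where its median went from -0.26 to -0.05; without siNC replicate 1 the median was -0.09 and the list stayed called (0.0129).

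Interferon-response genes had 12 of 21 members lower and 21 of 21 negative (19 lower adjusted over the list alone; camera adjusted p = 4.23e-09, and adjusted p = 0.174 with an estimated correlation). The antiviral genes MX2, IFIT1 and OAS2 and the RNA sensor DDX58 fell by 1.13, 0.70, 1.10 and 0.83. Either word was held by 3 of the 12, OAS2 among them, and the 17 members without one had a median of -0.74.

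YAP and TEAD targets had 10 of 17 members lower (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.61e-06, and adjusted p = 0.248 with an estimated correlation). WWTR1, itself the coactivator TAZ, tissue factor F3, the matricellular gene CCN2 and AJUBA fell by 0.94, 1.61, 1.38 and 0.85; WWTR1 and F3 held a word, as did 4 of the 10. Early TGF-beta targets had 7 of 16 members lower (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00137, and adjusted p = 0.471 with an estimated correlation), with CCN2, TGIF1 and SKIL falling by 1.38, 0.73 and 0.57. SKIL was not called without siSHMT2 replicate 3 (0.0566), with a log2 fold change of -0.54. Integrins and adhesion genes had 6 of 14 lower (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00135, and adjusted p = 0.174 with an estimated correlation). ITGB1, the common beta chain, fell from 43.2 ± 12.8 to 14.3 ± 1.88 FPKM (SD, n = 3). ITGA2, ITGAV and ITGB5 fell by 0.83, 1.10 and 0.47, and ITGAV held both words. ITGB5 was not called without siSHMT2 replicate 1 or 2 (0.0847 and 0.0572), with log2 fold changes of -0.43 and -0.47. Growth factor ligands and receptors had 6 of 17 lower (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00611, and adjusted p = 0.304 with an estimated correlation). The TGF-beta receptor TGFBR1, VEGFC, FGF2 and INHBA fell by 1.37, 1.20, 0.88 and 0.86; TGFBR1, FGF2 and INHBA held both words. The median of this list was -0.33, and -0.11 among the 13 members without a word, where the list stayed called (camera adjusted p = 0.0163). It was not called at a mean FPKM of at least 5 (median -0.04, adjusted p = 0.118) or with array weights (median -0.15, 0.0539), and over the alternatives its median ran from -0.67 to -0.03.

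Matrix proteases and their inhibitors had 7 of 14 members lower and 1 higher (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00135, and adjusted p = 0.174 with an estimated correlation). The plasminogen activators PLAT and PLAU fell by 1.60 and 1.60, and the inhibitor TIMP3 rose by 0.55. Its rise was not called without siSHMT2 replicate 1 (adjusted p = 0.0537), with a log2 fold change of 0.55. TIMP1 was 990 ± 383 and 654 ± 85.7 FPKM (limma adjusted p = 0.258). Collagens were not called as a list by camera (2 of 14 lower, 3 adjusted over the list alone; camera adjusted p = 0.15), but were by fry (adjusted p = 0.0366). COL6A3, which held GACTTTA, and COL6A1 fell by 1.04 and 0.70. COL1A1 was 221 ± 27.6 and 206 ± 22.0 FPKM (adjusted p = 0.694), COL1A2 6.78 ± 1.37 and 7.98 ± 0.393 (adjusted p = 0.319) and COL3A1 6.04 ± 1.44 and 6.67 ± 0.582 (adjusted p = 0.598; limma, SD, n = 3). TGFB1 was 109 ± 18.5 and 114 ± 13.7 FPKM (adjusted p = 0.803).

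Stellate cell activation markers were mixed, with 2 of 16 lower and 1 higher (the same counts adjusted over the list alone; camera adjusted p = 0.349). TPM1 and vimentin (VIM) fell by 1.27 and 0.71 and calponin CNN1 rose by 0.92. VIM was not called without siNC replicate 3 (adjusted p = 0.0509) or siSHMT2 replicates 1, 2 or 3 (0.0775, 0.0949 and 0.0878). Its log2 fold change was -0.75 to -0.67 in these. ACTA2, the smooth muscle actin of activated stellate cells, lay below the filter, at 0.209 to 0.555 FPKM in siNC and 0.510 to 0.985 in siSHMT2, from 9 to 47 reads. Collagen processing genes had 2 of 18 lower and 1 higher (camera adjusted p = 0.43), and quiescence markers 0 of 6 called (adjusted p = 0.711).

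Mitotic genes had 15 of 33 members lower and 31 negative (15 adjusted over the list alone; camera adjusted p = 7.36e-08, and adjusted p = 0.231 with an estimated correlation). The kinesins KIF2C and KIF23, the kinase PLK1 and CDC20 fell by 1.25, 0.99, 0.71 and 0.82, and 4 of the 15 held a word, KIF2C among them. The proliferation marker MKI67 fell by 0.49 (adjusted p = 0.0181), but was not called without siSHMT2 replicate 1, 2 or 3 (adjusted p = 0.0864, 0.0762 and 0.0820). Its log2 fold change in these was -0.50, -0.48 and -0.48. DNA replication genes were not called as a list by camera (2 of 34 lower, 1 higher; camera adjusted p = 0.589), though RRM2, a ribonucleotide reductase subunit that held ACTTTAA, fell by 1.40. Histone genes had 3 of 9 lower (camera adjusted p = 0.0275, and adjusted p = 0.245 with an estimated correlation), a list not called without siNC replicate 3 (0.0642) or siSHMT2 replicate 2 (0.0530), or at a mean FPKM of at least 5 (0.152), with its median between -0.41 and -0.38 in each against -0.40. Among p53 targets 3 of 17 were lower and 1 higher (camera adjusted p = 0.424); the cell cycle inhibitor CDKN1A, which held GACTTTA, fell by 1.29. Apoptosis regulators had 4 of 16 higher and 3 lower (camera adjusted p = 0.955), with BCL2L1 rising by 0.86 and XIAP, which held both words, and BIRC2 falling by 0.98 and 0.75.

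Serine synthesis and uptake genes had 3 of 10 members lower (4 adjusted over the list alone; camera adjusted p = 0.00293, and adjusted p = 0.245 with an estimated correlation). PSAT1, the aminotransferase of serine synthesis, fell by 2.10, and the phosphatase PSPH and the mitochondrial serine carrier SFXN1, which both held a word, by 1.11 and 1.02. PHGDH, the first enzyme of the pathway, was 35.2 ± 8.42 and 29.2 ± 3.64 FPKM (limma adjusted p = 0.431, SD, n = 3). The mitochondrial folate pathway had 2 of 8 lower, SHMT2 itself and MTHFD2 (3 adjusted over the list alone; camera adjusted p = 0.0331, and adjusted p = 0.245 with an estimated correlation). Without SHMT2 the other 7 members gave a camera adjusted p of 0.195, and the list was not called without siNC replicate 1 (0.0853), with array weights (0.0945), with voom quality weights (0.0827) or with the GC trend removed (0.0551). Its median stayed between -0.30 and -0.25 in these, against -0.29, and was -0.03 without a filter, where the list stayed called (0.0160). MTHFD2 fell by 0.49 (limma adjusted p = 0.0473), was not called without siNC replicate 1, 2 or 3 (0.0881, 0.0606 and 0.0763) or siSHMT2 replicate 1 or 3 (0.154 and 0.166), and held ACTTTAA. Its log2 fold change was -0.54 to -0.39 in these. SHMT1, the cytosolic counterpart of SHMT2, lay below the filter at 0.253 to 1.04 FPKM. Cytosolic folate genes had 1 of 10 higher and 1 lower (camera adjusted p = 0.657), purine synthesis genes 2 of 12 lower (0.144) and methionine cycle genes 2 of 8 lower (0.0658).

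ATF4 was 185 ± 33.2 and 135 ± 3.14 FPKM (limma adjusted p = 0.0897, SD, n = 3), and 3 of 20 ATF4 targets were lower (camera adjusted p = 0.15), among them the secreted glycoprotein STC2, which fell by 1.26. The ATF4 list was called lower without siNC replicate 1 (0.0344) and among genes without the words (0.0435), with medians of -0.25 and -0.30 against -0.20. Chaperones of the endoplasmic reticulum had 4 of 18 lower (5 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.505 with an estimated correlation). HERPUD1 fell by 1.09 and held ACTTTAA; the list was not called without siNC replicate 1 (0.0624) or siSHMT2 replicates 1 or 3 (0.0638 and 0.0942), with medians of -0.14, -0.17 and -0.11 against -0.15. With TPM its median was -0.07 and it stayed called (0.0312).

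Nuclear genes of respiratory complex I had 3 of 30 members higher and 0 lower (2 adjusted over the list alone; camera adjusted p = 0.0163, and adjusted p = 0.596 with an estimated correlation). Their median of 0.23 became 0.09 without siNC replicate 1 (camera adjusted p = 0.331), 0.13 without siSHMT2 replicate 3 (0.111), 0.01 with array weights (0.368) and 0.03 with voom quality weights (0.219), and the list was not called in any of these. Among genes without the words the median stayed at 0.23, but the list was not called (0.103). The median of all genes in that fit was 0.0592, against 0.0182 in the main fit. Tricarboxylic acid cycle genes had 1 of 22 higher and 1 lower (list camera adjusted p = 0.0406, and adjusted p = 0.245 with an estimated correlation). The lower one was the citrate synthase CS, which held both words. CS was not called when any library but siNC replicate 2 was left out (limma adjusted p = 0.0530 to 0.164). Its log2 fold change was -0.43 to -0.33 there, against -0.40. The list of tricarboxylic acid cycle genes was not called without siNC replicate 1 (0.0506) or 2 (0.0510) or siSHMT2 replicate 3 (0.0644), at a mean FPKM of at least 5 (0.119), with quantile normalization (0.0575), array weights (0.103) or voom quality weights (0.0779), or among genes without the words (0.0613). Their median of 0.17 became 0.07 with array weights and 0.08 with voom quality weights, and was 0.14 to 0.19 in the others, 0.19 among genes without the words; with TPM it was 0.27 and the list stayed called (0.0330). Mitochondrially encoded subunits had 13 of 13 members negative but 1 called lower, MT-CYB (list camera adjusted p = 0.0385, and adjusted p = 0.552 with an estimated correlation). MT-CYB was not called when any library but siNC replicate 1 was left out (limma adjusted p = 0.073 to 0.195). Its log2 fold change was -0.87 to -0.62 there, against -0.72. The list of mitochondrially encoded subunits was not called without siNC replicate 1 (0.0853) or 3 (0.0593) or siSHMT2 replicate 2 (0.132) or 3 (0.111), without a filter (0.122), with quantile normalization (0.252), protein-coding genes only (0.0671), array weights (0.239) or voom quality weights (0.167), or with the GC trend removed (0.0520). Its median of -0.32 became -0.12 with quantile normalization, -0.20 with array weights and -0.22 with voom quality weights, and stayed between -0.32 and -0.25 in the others, at -0.29 with the GC trend removed. Mitochondrial reads made up 4.54% of reads in siSHMT2 replicates 2 and 3 and 5.47% to 6.01% in the other libraries.

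The remaining lists were not called by camera. Members higher and lower were 1 and 0 of 34 for respiratory complexes II to V (camera adjusted p = 0.105), 2 and 2 of 51 for the mitochondrial ribosome (0.134), 0 and 2 of 54 for cytosolic ribosomal proteins (0.144) and 1 and 2 of 22 for ribosome biogenesis (0.317). They were 0 and 2 of 19 for glutathione and NRF2 targets (0.0836), 1 and 0 of 19 for aminoacyl-tRNA synthetases (0.424), 0 and 1 of 14 for heat shock proteins (0.552) and 1 and 8 of 23 for immediate early genes (0.0658). They were 0 and 3 of 22 for cholesterol synthesis (0.317), 1 and 1 of 19 for fatty acid metabolism (0.691), 2 and 3 of 21 for glycolysis (0.317), 1 and 2 of 16 for hypoxia targets (0.144), 2 and 0 of 23 for autophagy (0.224) and 0 and 1 of 9 for RNA interference machinery (0.724). Markers of cholangiocytes had 1 of 7 lower (0.711). Of the other cell types, 0 hepatocyte markers, 1 leukocyte marker (CD14, not called) and 1 endothelial marker (TIE1, not called) passed the filter. The rotation test fry, which asks whether the members changed together, without comparing them with other genes, called 23 lists. These were 14 of the 16 that camera called, without complex I (adjusted p = 0.229) and the mitochondrially encoded subunits (0.0593), and 9 that camera did not call. The 9 were purine synthesis (0.0248), methionine cycle (0.0431), heat shock proteins (0.0159), collagens (0.0366), p53 targets (0.0248), immediate early genes (0.00665), cholesterol synthesis (0.0221), glycolysis (0.0238) and autophagy (0.00778).

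Of the 26 lists that camera did not call, 10 were called in at least 1 alternative. Cytosolic ribosomal proteins were called in 6 (lowest adjusted p = 0.000123, without siNC replicate 1, and 0.0458 among genes without the words), and immediate early genes and respiratory complexes II to V in 5 each (lowest 0.0107 and 0.0102). Glutathione and NRF2 targets were called in 4 (lowest 0.0307), methionine cycle genes in 3 (0.0399) and ATF4 targets in 2. Purine synthesis (0.0398, without a filter), the mitochondrial ribosome (0.0368, with TPM), hypoxia targets (0.0279, without siNC replicate 2) and ribosome biogenesis (0.0435, among genes without the words) were called in 1 each.

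**Figure D3:**
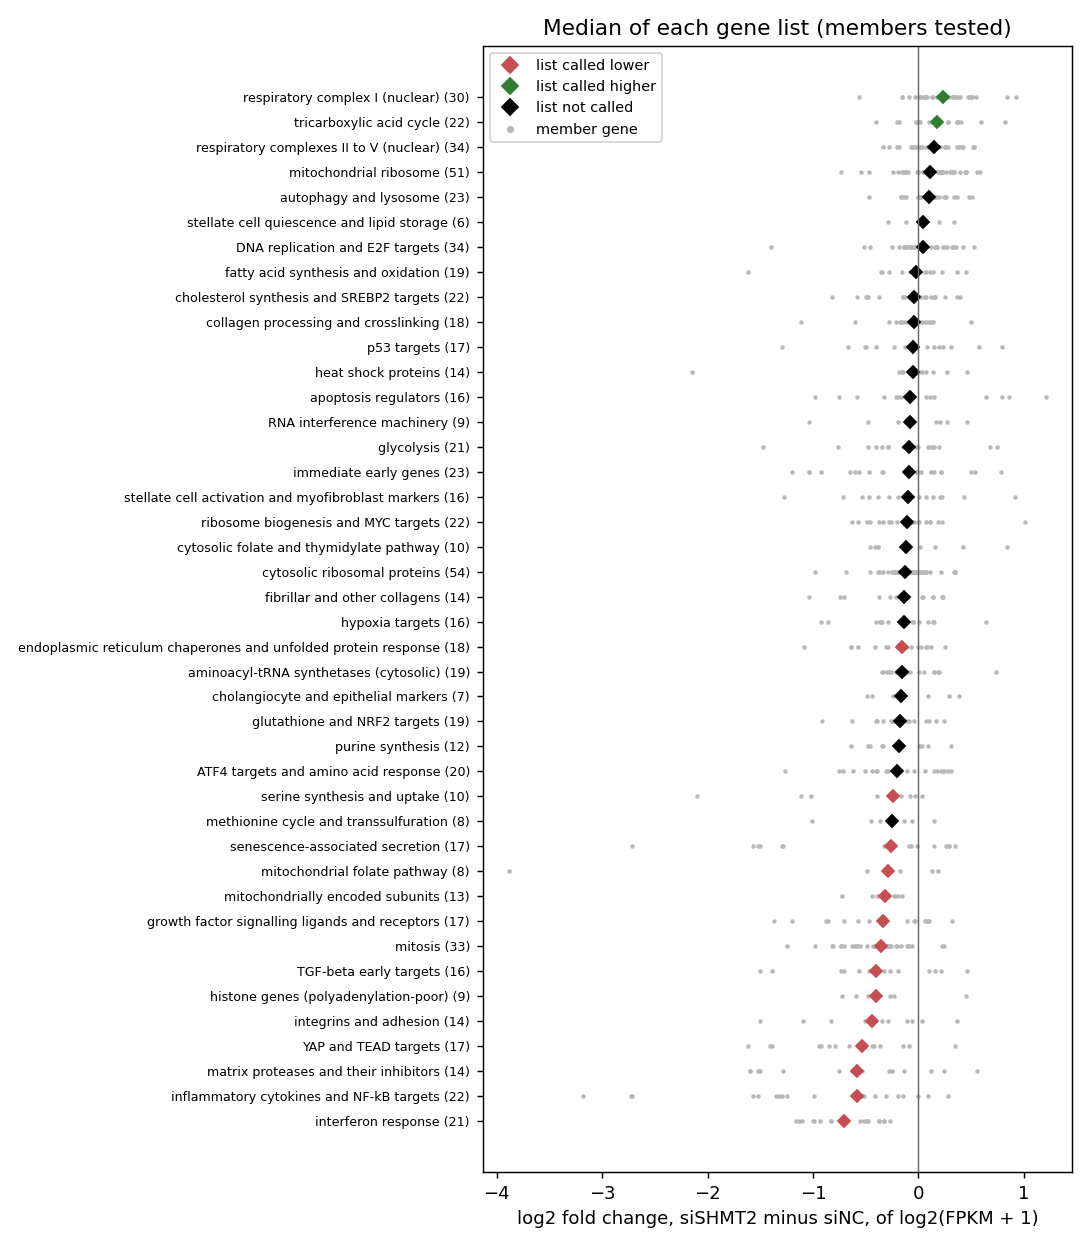
Log2 fold change (siSHMT2 minus siNC) of the tested members of each of 42 gene lists (grey points) and the list median (diamond), red for lists called lower by camera, green for those called higher and black for the rest. The interferon response has the lowest median (-0.70) and respiratory complex I the highest (0.23); with an estimated correlation 0 lists were called.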

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

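SHMT2 stayed lower in all 23 alternatives with a gene test (log2 fold change -4.38 to -3.75), and no called gene changed sign in any alternative. Of 125 other named genes called, 76 were called in every alternative that gave a value, and of the 16 called lists 8 were, at the preset correlation. With an estimated correlation 0 lists were called. Some of the lost lists had an estimate below the preset one, such as integrins (-0.0499), and others above it, such as complex I (0.43). A higher correlation between members therefore does not account for every loss. With an estimated correlation the test also has far fewer degrees of freedom, so these losses do not measure correlation between members. The cause of other changes was not tested unless stated.

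Leaving out 1 library in turn gave 229 to 729 genes higher and 498 to 1132 lower, 46 to 76 higher and 193 to 236 lower by at least 2-fold, 13 to 19 lists, and -3.98 to -3.75 for SHMT2. The at least 2-fold counts became 99 higher and 402 lower with a pseudocount of 0.1, and 109 and 423 with 0.01, since a smaller pseudocount compresses low genes less. Without a filter 333 genes were higher and 603 lower, with more genes tested. A mean FPKM of at least 5 gave 618 lower and 126 by at least 2-fold, with fewer genes tested, and no value for the mitochondrial folate list. TPM gave 620 lower and 117 higher by at least 2-fold. Array weights gave 1827 higher and 1976 lower.

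The replicate block gave 374 higher and 696 lower. Deviations of same-numbered libraries correlated at -0.018, -0.349 and 0.243, without a common sign. The labels do not say whether the numbers pair the samples, and these correlations cannot settle it.

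Of the alternatives chosen after seeing the data, voom on recovered reads gave 115 higher and 418 lower by at least 2-fold, and voom with quality weights 1639 higher and 1922 lower, 152 and 458 by at least 2-fold. Among SHMT2 and the searched protein-coding genes without either leading word, 428 genes were lower and 60 by at least 2-fold, of 7077 tested. The median of all genes was 0.0592 there, against 0.0182 in the main fit. List calls gained or lost in it therefore cannot be put down to the word holders alone.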

Other observations

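The base composition test was chosen after the word result was seen; the test of list members without the words was chosen after the word result but before its own. The leading pattern was the share of strongly lowered genes with GACTTTA or ACTTTAA in the 3′ UTR. An siRNA can lower transcripts other than its target through matches of its seed, the bases near the guide's 5′ end, to 3′ UTRs. The planned prediction was that a word of the SHMT2 transcript would go with lower fold change and be held more often by genes called at least 2-fold lower.

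GACTTTA had the lowest t of all words tested (-26.0). Genes with it differed from the others by -0.32 on the log2 scale after allowance for 3′ UTR length and GC content (adjusted p = 1.43e-139), and 50.8% of genes at least 2-fold lower held it against 10.9% of the others. GACTTTA was picked on these same fold changes, so these shares are not separate support. It lies in SHMT2 at chromosome 12, 57234059 to 57234065 (GRCh38), in the coding part of exon 11 of 12. The next word, ACTTTAA (t = -20.6), overlaps it by 6 bases and is not in SHMT2. A match of the siSHMT2 guide's seed to 3′ UTRs may therefore account for many of the lower genes; without the siRNA sequence this stays a hypothesis. Base composition alone was argued against: of 406 words made of the same bases, sharing fewer than 5 in a row with GACTTTA, the lowest t was -5.44. The GC trend between libraries was also argued against, since 88.1% of genes at least 2-fold lower stayed so after its removal.

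The planned rule was easy to meet, because 1454 words went with lower fold change and 164 of them occur in SHMT2. SHMT2 words were not in excess among them (11.3% against 17.0% of all words, exact hypergeometric test, p = 1). That excess had at first been required beside the planned rule, and was set aside after its result was seen, since it was not part of the prediction and a single guide has a single seed. The test was run in 2 forms. The first one run departed from the planned one by squared terms, transcript GC content and a limit to words held by at least 50 genes, and was written before any word result. The planned form was run after that result was seen, and gives the values above. In the form run first GACTTTA and ACTTTAA also ranked 1 and 2 (t = -25.7 and -19.9), with 80 of 638 words in SHMT2 and an exact hypergeometric p of 0.9996 for an excess. Since 17.0% of all words occur in SHMT2, a SHMT2 word in first place would not be unusual by itself, and the evidence rests on how far GACTTTA stands from the rest.

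The lower interferon, cytokine and YAP-target lists were not explained by the 2 leading words in the 3′ UTRs of their members. The members without either word had medians of -0.74, -0.54 and -0.51, the nearest to 0 being -0.509. Each list stayed called by camera at the preset correlation. Words that overlap GACTTTA also went with lower fold change (ACTTTAT, t = -12.05, and TGACTTT, t = -11.43), and coding sequences were not searched. Other seed matches in the members are therefore not excluded. Over all tested genes the 3 lists were not called with an estimated correlation (adjusted p = 0.174, 0.0775 and 0.248). The GC trend was argued against as well (median nearest 0 after removal, -0.583), as was 1 outlying siNC library (highest camera adjusted p at the preset correlation with any 1 library left out, 4.2e-05). An indirect effect of other lowered transcripts, such as TGFBR1 or WWTR1, which held both words, could not be separated from an effect of SHMT2 loss with 1 siRNA. With 0 libraries of untransfected cells, a rise of these lists in siNC cannot be told apart from a fall in siSHMT2.

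The words with the highest t were GGCAGGA (7.52), CGGAGAA (6.77) and TCGGAGA (6.69). The last pair overlap by 6 bases and were held by 248 and 209 genes, whose log2 fold changes were higher by 0.17 and 0.18. Without untransfected cells, higher values in siSHMT2 cannot be told apart from lower values in siNC, and the cause was not tested.

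Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real grouping, the real one itself, and the same held for 2-fold calls (1) and called lists (1). The real grouping called 1729 genes, 267 of them by at least 2-fold, and 16 lists; the highest other split called 0, 0 and 12. With 10 splits the share cannot go below 0.1. Camera at the preset correlation thus called up to 12 lists in groupings that mix both siRNAs. Each mixed split holds unequal numbers of the siRNAs on its sides, so part of the siRNA difference remains. The rest adds to the spread within each side. These splits therefore do not show how many genes or lists would be called without any difference.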
